A study of Homo sapiens with 56 samples.

How the data were processed

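The assay was eCLIP, in which cells are irradiated with ultraviolet light so that proteins crosslink to the RNA they touch, 1 protein is immunoprecipitated, and the RNA fragments that come with it are sequenced. The cells were HEK293T, an established human embryonic kidney line. Per the labels' protocols, cells were irradiated at 254 nm and 400 mJ/cm2, the lysate was treated with 40 U of RNase I, and 10 µg of antibody was used. RNA was taken from a membrane strip reaching 75 kDa above the protein's mass, and an aliquot of lysate saved before the immunoprecipitation (IP) became the size-matched input. The labels name 14 proteins with 2 replicates each, so there were 28 IP libraries and 28 input libraries. Nothing in the labels says that replicates came from separate cultures, so the p-values that compare libraries or proteins measure only the spread between these samples, which may be technical. The p-values of gene lists and of shared targets count genes within these samples and hold no spread between replicates. The labels of TOB1, NANOS3, BOLL and IFIT2 carry the prefix OE, which is not spelled out there, and the other 10 proteins carry none. The description labels also hold a sequencing lane number, with 6 different lanes over the 28 IP libraries, and both replicates of a protein share a lane.

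The authors deposited 1 peak list per IP library, without pooling replicates, and the input libraries enter only through the values in those lists. Each listed peak has a position, a strand, gene names, a transcript region, a log2 value that the authors give as the fold enrichment of the peak over its size-matched input, and the −log10 of a p-value that the authors give for the same comparison, capped at 400. Per the submitters' processing notes, reads were mapped with STAR to the human genome build hg19, and no version is given. The peak caller, the filters, the scaling of the libraries and the gene annotation are not given in the sources used here. No read counts were used, so the sequencing depth of each library is unknown, and the number of listed peaks is the only measure of how much each file holds. In all, 4946983 peaks were listed, and 1.78% of them carried more than 1 gene name. Only 0.037% were placed outside genes, so RNA from the strand opposite to a gene is hardly represented in these lists.

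A peak was called enriched when the authors' log2 fold was at least 3 (8-fold) and their −log10 p at least 3 (p of 0.001). A peak was called reproducible when an enriched peak of replicate 1 overlapped an enriched peak of replicate 2 by at least 1 nt on the same strand. A target gene of a protein was a gene with at least 1 reproducible enriched peak, leaving out peaks with more than 1 gene name and peaks outside genes. Folds were used to filter, describe and rank peaks within a list, and lists of different proteins were compared by overlap. Coordinates are 1-based on hg19, and region names are those of the deposited files, grouped into 5' UTR, coding sequence (CDS), 3' UTR, intron and noncoding exon. Peaks with other labels, such as introns of noncoding genes and microRNAs, count in the total of a library but were not tested as a region.

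Agreement between libraries was measured by the Jaccard index of their sets of genes with an enriched peak, which is the number of shared genes over the number in either set. Its mean over same-protein pairs was compared with 100000 random pairings of the libraries in a one-sided permutation test. Lane was checked as a batch by permuting the lanes of the 14 proteins. Shares of enriched peaks by region were averaged per protein and compared between 7 proteins of deadenylation and decay (CNOT7, PARN, TOB1, TOB2, NANOS3, DDX6 and MEX3C) and 7 others, and between the 4 proteins with the OE prefix and the 10 without, by two-sided exact permutation tests with Benjamini-Hochberg adjustment over 10 tests. Shares of single libraries were given 95% Wilson intervals, which cover counting error only. Target genes were counted in 24 gene lists with Fisher's exact test (two-sided), against all genes with a listed peak in both replicates. A list was tested for a protein when at least 5 of its members were measured, which gave 326 tests adjusted together. As an alternative, each list was set against 10000 random lists matched on the number of listed peaks per gene in 10 strata, because a gene with more listed peaks has more chances to hold an enriched one. Shared targets of 2 proteins were tested with Fisher's exact test over genes listed in all 4 libraries, adjusted over 91 pairs, with a Mantel-Haenszel test over the same strata as an alternative.

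The genes named for each protein follow a rule fixed before the data were examined. They are up to 5 genes with the reproducible peaks of highest fold (taking the smaller of the 2 replicates' folds), up to 5 protein-preferred genes, up to 4 members of each list enriched among the targets, and the protein's own gene. For BOLL, members are named for 3 of its 16 lists only, for length. Some genes that the rule selects are not reported here. The protein-preferred genes were planned as a limma test of each gene's highest log2 fold in a protein's 2 libraries against the other 26, asking for an adjusted p under 0.05 and a difference of at least 1. The fit was computed on genes with missing libraries as well. On simulated values, its p-values for the contrast of DDX6 differed from those of limma's lmFit by at most 8.88e-16 on the 2790 complete genes. That test was run as planned and then set aside, after its counts had been seen, because a fold is comparable within its own list and the calls followed the scaling of the lists. For BOLL, limma called 1280 genes (adjusted p threshold 0.05) when libraries were centred on their medians and 7658 when they were not. Its totals are given only among the alternatives. The second part of the rule was replaced, also after seeing the data, by an overlap criterion. It takes target genes with no enriched peak in any library of the other 13 proteins, among genes listed in at least 20 libraries, ranked by the smaller fold. The cut-offs of 4 and 6 proteins for positions shared between proteins were likewise chosen after seeing the data. A planned search for sequence motifs in the peaks, with its 100 nt window alternative, was not run because no hg19 genome sequence was used here.

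The tests were checked on simulated data. In the simulated limma contrast of DDX6 with the other proteins over 10927 genes, 88% of genes raised by 2 on the log2 scale were recovered and 100% of those raised by 4, with 5 false calls for DDX6. For the gene list tests, 13000 simulated genes were given targets at a rate that rose with the number of listed peaks. In a first setting, with 4.49% of genes as targets and lists raised 4-fold in odds, Fisher's test and the matched lists each recovered 6 of 20 raised lists of 40 genes and called 0 of 20 peak-rich lists. A second setting was added after this low recovery, with 13.03% of genes as targets and lists raised 8-fold. There, both tests recovered 20 of 20 raised lists, while Fisher's test also called 10 of 20 lists that were merely rich in listed peaks and the matched lists called 0. Moderate enrichments in proteins with few targets can therefore be missed, and a call by Fisher's test alone can reflect the number of listed peaks.

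The alternatives were a looser fold (log2 of at least 1), a stricter p (−log10 of at least 5), a reciprocal overlap of 50%, each replicate alone, correlations in place of the Jaccard index, shares of peak length, the 10 proteins without the prefix alone, the matched lists, the Mantel-Haenszel strata, the limma settings and, added after seeing the data, leaving out positions enriched with 4 or more proteins. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.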

Results

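RNA bound by 14 proteins was mapped by eCLIP in HEK293T cells, in a series on factors that set mRNA stability and translation, with 2 IP libraries and 2 size-matched inputs for each protein. CNOT7 and PARN are deadenylases, TOB1 and TOB2 are adaptors of the CCR4-NOT deadenylase complex, NANOS3 and BOLL are germline RNA-binding proteins, and DDX6 is a helicase of P-bodies. MEX3C carries KH domains and a RING finger, AIMP1 is a scaffold of the aminoacyl-tRNA synthetase complex, and MTDH is a membrane-associated protein. UBAP2L is a stress granule protein, CLK3 a kinase of splicing factors, SNRPA a protein of the U1 small nuclear ribonucleoprotein, and IFIT2 an interferon-induced protein. The deposited lists held between 11185 peaks (TOB2 replicate 1) and 420590 peaks (DDX6 replicate 2) per library. All folds below are the authors' log2 enrichment of a peak over its own input.

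The first comparison asked which RNA positions were enriched in the IP over input in both replicates. BOLL had by far the most reproducible enriched peaks, 34085 in 7436 target genes, from 51286 and 51565 enriched peaks in its 2 libraries. UBAP2L followed with 12633 peaks in 2396 target genes, MTDH with 7002 in 1439, MEX3C with 3272 in 1736 and NANOS3 with 2339 in 929. SNRPA had 1874 peaks in 610 target genes, DDX6 1041 in 571, CLK3 798 in 114 and AIMP1 561 in 282. The fewest were found for TOB2 (346 in 116 genes), CNOT7 (333 in 153), IFIT2 (269 in 173), TOB1 (179 in 128) and PARN (136 in 76). The replicates of UBAP2L were uneven, with 22342 enriched peaks in replicate 1 and 47201 in replicate 2. These counts rest on 1 fixed fold cut-off, while the lists differ in scale. The median log2 fold of listed peaks ran from -0.147 (SNRPA replicate 1) to 2.462 (MTDH replicate 2), with 2.004 and 1.663 for BOLL. Of the listed peaks, 21.8% and 19.7% were enriched for BOLL, against 0.93% and 1.12% for SNRPA. The order of the proteins by count can therefore reflect the scaling of the lists.

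Part of these peaks lay at positions that were enriched with several proteins. Among reproducible peaks, 87.8% of those of SNRPA, 73.8% of UBAP2L, 68.4% of BOLL and 66.7% of MTDH overlapped no enriched peak of another protein. For TOB1 this share was 2.23%, for TOB2 7.80%, for CNOT7 12.9%, for IFIT2 17.8% and for PARN 23.5%. Without the positions enriched with 4 or more proteins, TOB1 was left with 75 peaks, PARN with 70, TOB2 with 173 and IFIT2 with 179, while MTDH kept 6917 and BOLL 33553. The median width of the reproducible TOB2 peaks was 11 nt, against 46 nt for BOLL and 61 nt for UBAP2L, but TOB1 and IFIT2 peaks were not narrow (52 and 64 nt).

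**Figure D1:**
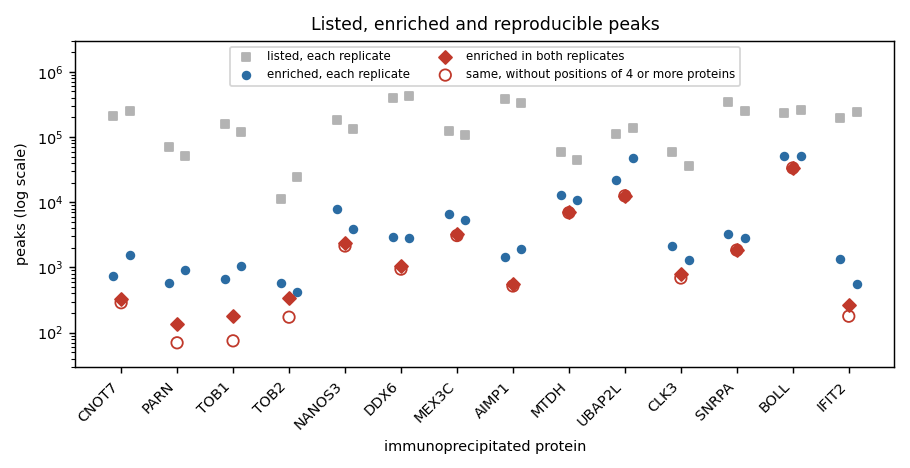
Number of peaks (log scale) for each of the 14 proteins: listed and enriched peaks in each replicate, peaks enriched in both replicates, and the same without positions enriched with 4 or more proteins. BOLL has 34085 peaks enriched in both replicates and PARN 136, of which 70 are left without the shared positions.

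Replicates of a protein shared more enriched genes than libraries of different proteins. The mean Jaccard index of the 14 same-protein pairs was 0.403, from 0.121 for PARN, 0.164 for TOB1 and 0.194 for IFIT2 to 0.582 for UBAP2L and 0.845 for BOLL. The mean over pairs of different proteins was 0.0851, and the highest mean among the random pairings was 0.232 (permutation test, one-sided, p = 1e-05, the smallest it can give). For 27 of the 28 libraries the most similar library was the other replicate. The exception was CNOT7 replicate 2, whose index was 0.315 with DDX6 replicate 2 and 0.275 with its own replicate 1. The title of that CNOT7 library carries both R1 and rep2, and it was read as replicate 2. By this index of enriched genes, libraries of different proteins were no more alike within a sequencing lane (0.0627 over 12 protein pairs) than across lanes (0.0885, permutation test, one-sided, p = 0.936). The index does not see listed peaks below the thresholds. It also depends on the sizes of the sets, which ran from 184 genes (TOB2 replicate 2) to 8877 (BOLL replicate 2). Between sets of very unequal size it is low by construction, and its values do not rank the proteins by reproducibility.

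**Figure D2:**
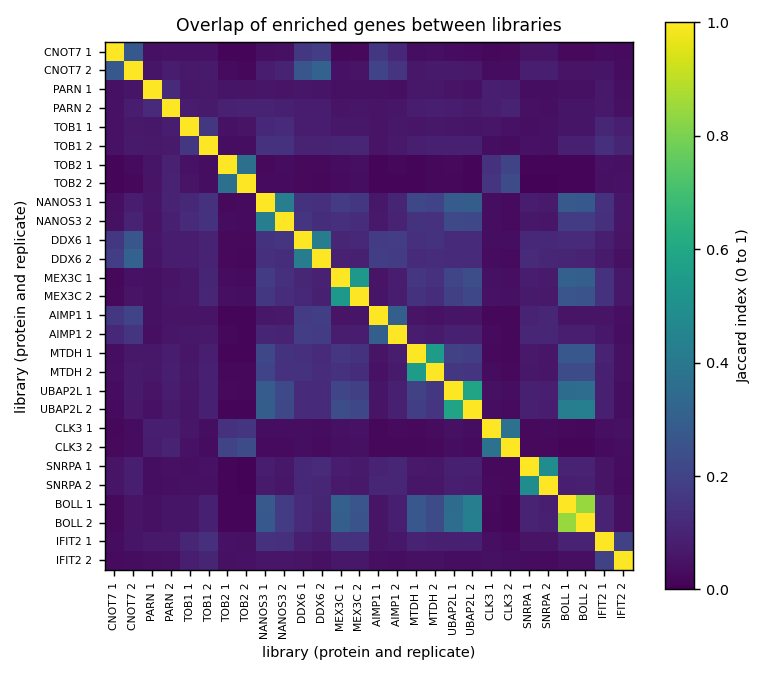
Jaccard index (0 to 1) of the sets of genes with an enriched peak for every pair of the 28 libraries, named by protein and replicate. The bright blocks next to the diagonal are replicates of a protein, from 0.121 for PARN to 0.845 for BOLL.

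The regional distribution asked where on transcripts each protein was enriched. Coding sequence held 95.1% ± 0.65 of the enriched peaks of UBAP2L, 93.9% ± 0.96 of MTDH and 89.0% ± 2.95 of CLK3 (mean ± SD, n = 2 for each protein), against 78.6%, 76.4% and 55.9% of their listed peaks. The 3' UTR held 86.7% ± 2.28 of the MEX3C peaks, 63.1% ± 1.59 of BOLL, 59.8% ± 7.98 of IFIT2 and 54.6% ± 10.2 of TOB1, against 37.2%, 34.0%, 13.8% and 17.6% of the listed peaks. NANOS3 peaks were divided between CDS (51.6% ± 1.41) and 3' UTR (37.2% ± 0.87). Introns held 69.0% ± 0.10 of the SNRPA peaks, 53.7% ± 6.23 of DDX6, 52.3% ± 5.48 of CNOT7 and 51.6% ± 0.99 of AIMP1. For DDX6, CNOT7 and AIMP1 this was below the intron share of the listed peaks (70.6%, 60.6% and 69.8%), and for SNRPA it was close to it (65.8%). Noncoding exons held 23.8% ± 7.05 of the CNOT7 peaks, against 2.21% of its listed peaks. For PARN and TOB2 the CDS held 44.4% ± 0.14 and 45.5% ± 0.71, against 42.8% and 38.5% of their listed peaks, so for PARN the share was close to that of the list. Part of these CDS peaks lay in the BOLL gene, which is described with the proteins' own transcripts. It held 33 of 262 and 40 of 197 in the TOB2 libraries and 33 of 400 in PARN replicate 2.

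Between protein classes, no regional difference passed the adjusted threshold. The 5' UTR share was 6.26% ± 3.42 for the deadenylation and decay proteins (SD, n = 7) and 3.12% ± 1.35 for the others (n = 7), with p = 0.039 and adjusted p = 0.195 (exact permutation test, two-sided). The 3' UTR share was 53.6% ± 11.5 for the 4 proteins with the OE prefix and 17.2% ± 25.4 for the 10 without (exact permutation test, p = 0.034, adjusted p = 0.195). The CDS share was 26.1% ± 20.6 for the decay proteins and 48.7% ± 42.1 for the others (exact permutation test, adjusted p = 0.424).

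**Figure D3:**
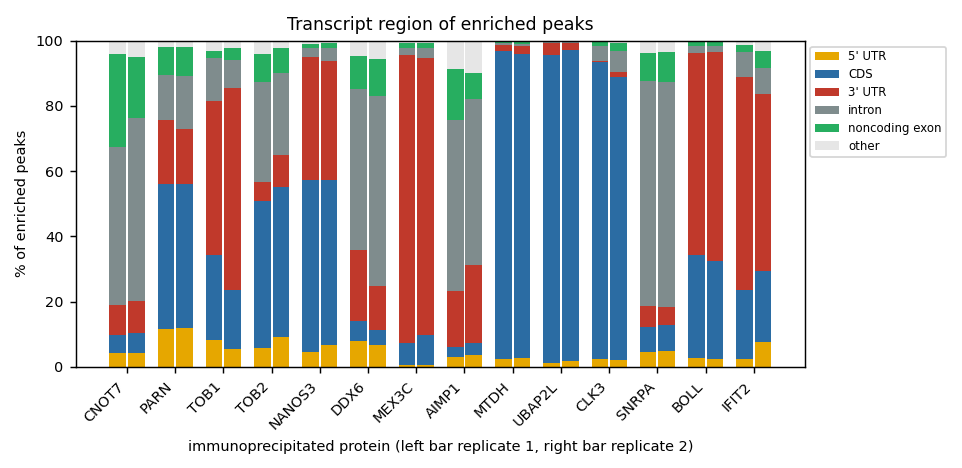
Percent of enriched peaks in each transcript region, with replicate 1 as the left and replicate 2 as the right bar of each protein. MTDH, UBAP2L and CLK3 are mostly CDS, MEX3C is 86.7% 3' UTR on average, and intron is the largest region for SNRPA, DDX6, CNOT7 and AIMP1.

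The next comparison asked which groups of genes the targets of each protein belonged to. Of 326 tests of a protein with a gene list, 45 lists held more targets and 11 fewer than the share of targets among all measured genes, at an adjusted p under 0.05 in Fisher's exact test. With random lists matched on listed peaks, 28 were higher and 10 lower, and 25 and 5 of these were also called by Fisher's test. Values named "matched" below are the adjusted p from those random lists.

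MTDH targets included genes of the secretory pathway and the cell surface, bound in their coding sequence. Of 45 measured genes for endoplasmic reticulum (ER) chaperones, the translocon and secretory folding, 39 were targets against 8.45 expected (Fisher's exact test, adjusted p = 2.45e-20, matched 0.0038). HSPA5, which encodes the ER chaperone BiP, held 33 reproducible peaks, the strongest at 9:128002955-128002971 in the CDS with log2 folds of 7.68 and 7.58. PDIA6 and PDIA4, protein disulfide isomerases, held 27 and 15 peaks, and SSR4, a subunit of the translocon-associated complex, held 14. Among membrane glycoproteins and receptors 36 of 47 were targets against 8.82 expected (adjusted p = 1.05e-15, matched 0.0038), with 27 peaks in BSG, 15 in LAMP1, 38 in SLC3A2 and 36 in APP.

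Further MTDH targets were replication-dependent histone genes, 26 of 40 against 7.51 expected (adjusted p = 1.04e-08, matched 0.0038), among them HIST1H2AB, HIST1H3A, HIST1H2AE and HIST1H3H. Cholesterol biosynthesis genes gave 14 of 24 against 4.50 (adjusted p = 0.00029, matched 0.0458), including DHCR7, SCD and SREBF1. Cytosolic ribosomal protein genes gave 45 of 74 against 13.9 (adjusted p = 9.54e-14, matched 0.0038), with RPS6, RPS15A, RPL13 and RPS29 leading by fold. The RPS6 and RPS15A peaks lay at positions enriched with 8 and 4 proteins. HLA class I genes gave 6 of 7 against 1.31 (adjusted p = 0.00226), among them HLA-C, HLA-B and B2M, but the matched value was 0.0619. C2H2 zinc finger genes were fewer, 3 of 94 against 17.6 (adjusted p = 0.000213, matched 0.0317). Spliceosome core genes (1 of 37), SR and hnRNP genes (4 of 40), stress granule genes (3 of 28), translation factors (5 of 39) and mitosis genes (5 of 46) were fewer with matched lists (0.0317 or lower) and not by Fisher's exact test. Of 1360 MTDH targets listed in at least 20 libraries, 35 had no enriched peak with any other protein, led by APOE (10 peaks), SIL1, PLTP, COL4A6 and RP5-1103G7.4. The strongest MTDH peaks also included B3GNT1 and, at positions enriched with 9, 10 and 4 proteins, FGFR3, SIN3B and KL.

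UBAP2L also bound coding sequence, and cytoskeleton genes were the only list called higher among its targets by both tests. Its strongest peaks lay in FLNA, TLN1, PLEC, ITPR3 and MDN1, and the FLNA peak at X:153588008-153588014 in the CDS had log2 folds of 6.29 and 7.06. Of 35 cytoskeleton genes, 25 were targets against 7.48 expected (Fisher's exact test, adjusted p = 1.62e-08, matched 0.0163), with 62 peaks in the dynein heavy chain gene DYNC1H1, 54 in FLNA and 35 in PLEC. ER genes, by contrast, gave 0 of 44 against 9.40 (adjusted p = 0.000644, matched 0.0057), and cytosolic ribosomal protein genes 1 of 77 (adjusted p = 9.74e-06, matched 0.0038). Both calls were lost at the looser fold, with 13 of 44 (adjusted p = 0.134) and 34 of 77 (adjusted p = 1.0).

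Some UBAP2L groups were called by Fisher's exact test alone. These were the aminoacyl-tRNA synthetase genes, 13 of 23 against 4.91 (adjusted p = 0.00225, matched 0.611; VARS, IARS, AARS and MARS), and deadenylation, decapping and P-body genes, 18 of 44 against 9.40 (adjusted p = 0.0217, matched 0.940; CNOT1, EDC4, TNRC6B and TNRC6A). Glycolysis genes gave 9 of 18 (adjusted p = 0.0434, matched 1.0; HK1, HK2, PFKP and PKM). Fewer targets by Fisher's test alone were found among small structured noncoding RNAs, 0 of 23 against 4.91 (adjusted p = 0.0479, matched 1.0), and histone genes, 2 of 42 against 8.97 (adjusted p = 0.0434, matched 1.0). The small RNA call was lost without the shared positions, and the histone call turned at the looser fold (33 of 42, higher). C2H2 zinc finger genes gave 57 of 263 against 56.2, higher with matched lists alone (0.0057). Of 2340 widely listed UBAP2L targets, 67 had no enriched peak with another protein, led by DHX16, GREB1, TIGD5, ZNF786 and IRS4.

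BOLL bound 50.5% of the genes it was measured on, with most of its enriched peaks in the 3' UTR. Of 23 lists, 16 held more targets and 3 fewer, and 9 of the 16 were also called with matched lists. Among those 9, nuclear-encoded oxidative phosphorylation genes gave 61 of 74 against 37.4 expected (Fisher's exact test, adjusted p = 5.25e-07), mitosis and DNA replication 45 of 49 against 24.8 (adjusted p = 3.94e-08), and proteasome subunits 28 of 31 against 15.7 (adjusted p = 8.51e-05). Strong peaks of these groups lay in the 3' UTR of UQCR10, ATP5G3 and UQCRH, of PRC1, CDKN1A, CCNE1 and AURKA, and of PSMB1, PSMA4, PSMA2 and PSMD8. The AURKA position was enriched with 6 proteins. The PSMB1 peak at 6:170844214-170844268 had log2 folds of 6.34 and 6.52. Cytosolic chaperones gave 28 of 30, cytoskeleton 33 of 35, glycolysis 18 of 19, ER genes 41 of 45, deadenylation and decay 39 of 44 and ribosomal proteins 58 of 78, each with a matched value of 0.048 or lower. Called by Fisher's exact test alone were translation factors (34 of 39), aminoacyl-tRNA synthetases (21 of 23), stress granule genes (26 of 29), spliceosome core genes (31 of 38), SR and hnRNP genes (37 of 43), membrane glycoproteins (37 of 48) and cholesterol biosynthesis (21 of 26), the last of which was lost without the shared positions. Histone genes gave 32 of 46 against 23.2, called with matched lists alone (0.0038).

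C2H2 zinc finger genes were fewer among BOLL targets, 115 of 418 against 211.1 expected (Fisher's exact test, adjusted p = 8.01e-20, matched 0.0038). Mitochondrially encoded transcripts gave 0 of 15 against 7.58 (adjusted p = 0.000353, matched 0.115) and small structured noncoding RNAs 3 of 24 against 12.1 (adjusted p = 0.00138, matched 1.0). The strongest BOLL peaks lay in KCTD1, C12orf57, RPLP1, FRMPD4 and MIR221, with C12orf57 and MIR221 at positions enriched with 5 and 6 proteins. Of 6966 widely listed targets, 587 had no enriched peak with another protein, led by C6orf1, UQCR10, BEX2, UQCRH and ZMAT2.

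The strongest SNRPA peaks lay in introns and in its own 3' UTR. Its strongest peak lay in an intron of GPI, which encodes glucose-6-phosphate isomerase, at 19:34876908-34876921 with log2 folds of 8.08 and 7.94, and GPI held 151 reproducible peaks. The next was in the 3' UTR of SNRPA itself, at 19:41271216-41271220 with log2 folds of 7.28 and 7.05; the protein is known to bind there. UBE2G2, DKC1 and GET4 followed, all in introns. Of 43 genes for SR proteins, hnRNPs and CLK kinases, 11 were targets against 1.79 expected (Fisher's exact test, adjusted p = 2.31e-05, matched 0.0057), with 20 peaks in HNRNPA2B1, 14 in HNRNPH1, 10 in PTBP2 and 6 in SRSF1. Small nucleolar RNA host genes gave 4 of 16 against 0.664 (adjusted p = 0.0255, matched 0.0316), namely GNL3, SNHG15, SNHG17 and SNHG1. Of 582 widely listed targets, 46 had no enriched peak with another protein, led by the noncoding genes RP4-717I23.3 (25 peaks), SDHAP3, RP5-1057J7.6, TMEM161B-AS1 and CTD-2020K17.1.

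DDX6 targets included small structured noncoding RNAs, translation factor genes and SR and hnRNP genes. Small structured noncoding RNAs gave 9 of 33 against 1.30 expected (Fisher's exact test, adjusted p = 6.66e-05, matched 0.0038), with 10 peaks in SCARNA2, 7 in SNORD17 and 6 each in SCARNA7 and SCARNA10. Translation initiation and elongation factors gave 8 of 38 against 1.49 (adjusted p = 0.00105, matched 0.010), the strongest being a 5' UTR peak of PABPC1, the cytoplasmic poly(A)-binding protein gene, at 8:101734263-101734306 with log2 folds of 5.64 and 5.28, then EIF1, EIF3E and EEF1D in introns. SR and hnRNP genes gave 8 of 42 against 1.65 (adjusted p = 0.00193, matched 0.0398), with HNRNPA0, HNRNPF, HNRNPU and HNRNPM leading.

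Further DDX6 groups passed Fisher's exact test only. These were nuclear long noncoding RNAs (4 of 12, adjusted p = 0.00704, matched 0.0667; SCARNA2, NEAT1, JPX and LINC00657), stress granule genes (5 of 29, adjusted p = 0.0333, matched 0.271; PABPC1, PRRC2B, ATXN2L and ATXN2), decay genes (6 of 44, adjusted p = 0.0434, matched 0.250; among them TNRC6C, BTG2 and ZFP36L2) and ER genes (6 of 45, adjusted p = 0.047, matched 0.141; HYOU1, SDF2L1, PDIA3 and CANX). The decay call was also lost without positions enriched with 4 or more proteins and at the looser fold. The strongest DDX6 peaks lay in MIR222, at a position enriched with 9 proteins, TMEM38A, XIST, the microRNA cluster MIR17HG and ZNF703. Of 532 widely listed targets, 8 had no enriched peak with another protein, led by RP11-108K14.4, STAG3L2, RNA5SP248, SCARNA13 and ABC7-42389800N19.1.

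CNOT7 had a larger share of noncoding exons among enriched than among listed peaks, and NEAT1 and XIST alone held 79 and 18 of its 333 reproducible peaks. Its strongest peaks lay in CCDC40, XIST, NEAT1, SNHG16 and ADAMTS1, the last at a position enriched with 7 proteins. Small nucleolar RNA host genes gave 3 of 14 against 0.174 expected (Fisher's exact test, adjusted p = 0.00517, matched 0.0121), namely SNHG16, GAS5 and SNHG1, with GAS5 at a position enriched with 6 proteins. Small structured noncoding RNAs gave 3 of 32 (adjusted p = 0.0434, matched 0.0879), namely SNORD17, SCARNA2 and RNU1-4. Of 141 widely listed targets, STAG3L5P and DRD4 had no enriched peak with another protein.

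AIMP1 was enriched in the 3' UTRs of genes for splicing factors and ribosomal proteins. SR and hnRNP genes gave 7 of 43 against 0.859 expected (Fisher's exact test, adjusted p = 0.00029, matched 0.0057), with SRSF1 at 17:56080815-56080839 in the 3' UTR (log2 folds 7.35 and 7.11), HNRNPA3, HNRNPU and HNRNPDL. Ribosomal protein genes gave 7 of 67 against 1.34 (adjusted p = 0.00315, matched 0.0038), with 3' UTR peaks in RPL38, RPS23, RPL41 and RPS24. Small nucleolar RNA host genes gave 3 of 15 (adjusted p = 0.0217, matched 0.018), namely SNHG3, SNHG16 and SNHG17. Other strong peaks lay in RP4-561L24.3, C7orf55-LUC7L2, RP11-217B1.2 and LIMD1-AS1, with RP4-561L24.3 and RP11-217B1.2 at positions enriched with 7 proteins. Of 267 widely listed targets, 7 had no enriched peak with another protein, led by EPHA6, SPATA5, HOXB4, RANBP17 and RPL36A.

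Most enriched MEX3C peaks lay in 3' UTRs. NFKBIA, which encodes an inhibitor of NF-kappaB, had a 3' UTR peak at 14:35871057-35871118 with log2 folds of 8.92 and 8.11. Cytosolic ribosomal protein genes were fewer among its targets, 1 of 77 against 11.1 expected (Fisher's exact test, adjusted p = 0.00136, matched 0.0057). At the looser fold this call turned, with 33 of the 77 as targets (adjusted p = 0.0364, higher). Called by Fisher's test alone were membrane glycoproteins and receptors (18 of 48, adjusted p = 0.000814, matched 0.0682; among them LRP5, LRP6 and EGFR) and deadenylation and decay genes (16 of 44, adjusted p = 0.00226, matched 0.134; NANOS3, TOB1, TNRC6B and DCP1A). The NANOS3 member rests on CDS peaks that are described with the proteins' own transcripts, and the EGFR position was enriched with 4 proteins. Oxidative phosphorylation genes (3 of 74 against 10.7, adjusted p = 0.0434, matched 0.138) and C2H2 zinc finger genes (26 of 320 against 46.3, adjusted p = 0.00536, matched 0.0682) were fewer by Fisher's test alone. The oxidative phosphorylation call was also lost without positions enriched with 4 or more proteins (adjusted p = 0.0598) and at the looser fold (0.268). The other strongest peaks lay in NANOS3 and, at positions enriched with 9 to 10 proteins, in RAB1B, FGFR3 and SIN3B. Of 1663 widely listed targets, 17 had no enriched peak with another protein, led by FGF9, GRHL1, FUT4, ZNF614 and PEX3, all in the 3' UTR.

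NANOS3 and IFIT2 both had cytosolic chaperone genes among their targets. IFIT2 gave 4 of 30 against 0.399 expected (Fisher's exact test, adjusted p = 0.00517, matched 0.0316), with 3' UTR peaks in DNAJA1, HSPH1, HSP90AA1 and DNAJB1. NANOS3 gave 7 of 29 against 2.17 (adjusted p = 0.0314, matched 0.215), led by DNAJB1 with 24 peaks, CCT3 with 16, HSPA4 and BAG3. The DNAJB1 peak of NANOS3 at 19:14626044-14626143 in the 3' UTR had log2 folds of 7.01 and 6.04. Of 323 measured C2H2 zinc finger genes, 34 were NANOS3 targets against 24.1 expected, called higher with matched lists (0.0231) and not by Fisher's exact test (adjusted p = 0.169). Strong NANOS3 peaks lay in its own gene, RP4-604G5.1, YTHDF1, ASCC3 and GKAP1, the last 3 at positions enriched with 4 to 5 proteins. Those of IFIT2 lay in MTOR, CAMK2D and, at positions enriched with 5 to 9 proteins, HES5, FGFR3 and RAB1B. Of 888 widely listed NANOS3 targets, 4 had no enriched peak with another protein (NUDT22, AC125232.1, SYTL1 and RP11-384K6.2), and of 168 IFIT2 targets 0.

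For TOB1, TOB2, PARN and CLK3 the strongest peaks were largely the same short positions. FGFR3, RAB1B and SIN3B, at positions enriched with 9 to 10 proteins, were among the strongest 5 genes of all 4 proteins. The TOB2 peak at 4:1806568-1806574 in the FGFR3 CDS had log2 folds of 11.15 and 10.51. The others were GKAP1 and ZNF512B for TOB1, JHDM1D and THSD7A for TOB2, THSD7A and HTT for CLK3, and CCDC40 and SLC38A10 for PARN. The SLC38A10 peak, in an intron at 17:79223434-79223498 with log2 folds of 7.57 and 7.16, overlapped no enriched peak of another protein.

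No gene list was called among the targets of PARN, TOB1 or TOB2 by Fisher's exact test or by matched lists, and at an unadjusted p under 0.05 there were 0, 0 and 1. This held only at the main fold for PARN and TOB1. At the looser fold, 50 of 75 measured cytosolic ribosomal protein genes were targets of PARN and 47 of 74 of TOB1 (Fisher's exact test, adjusted p = 2.08e-34 and 4.64e-28), as were 27 of 38 and 22 of 37 measured histone genes (adjusted p = 9.06e-20 and 1.85e-12). For TOB2 no list was called there either. Matched lists were not run at the looser fold. Its cut-off of 1 lay below the median log2 fold of the listed peaks of PARN (1.361 and 1.815) and TOB1 (1.085 and 1.238). CLK3 targets included 4 of 41 membrane glycoprotein genes, EGFR, IGF2R, LRP1 and NOTCH2, against 0.651 expected (Fisher's exact test, adjusted p = 0.027, matched 0.367), and the call was lost without the shared positions. Targets with no enriched peak of another protein were LAMA3, ANKRD36C, ZFHX4-AS1 and MT-TI for CLK3 (4 of 99 widely listed), MT-ND5 for TOB1 (1 of 118), and none of 75 for TOB2 and of 56 for PARN.

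**Figure D4:**
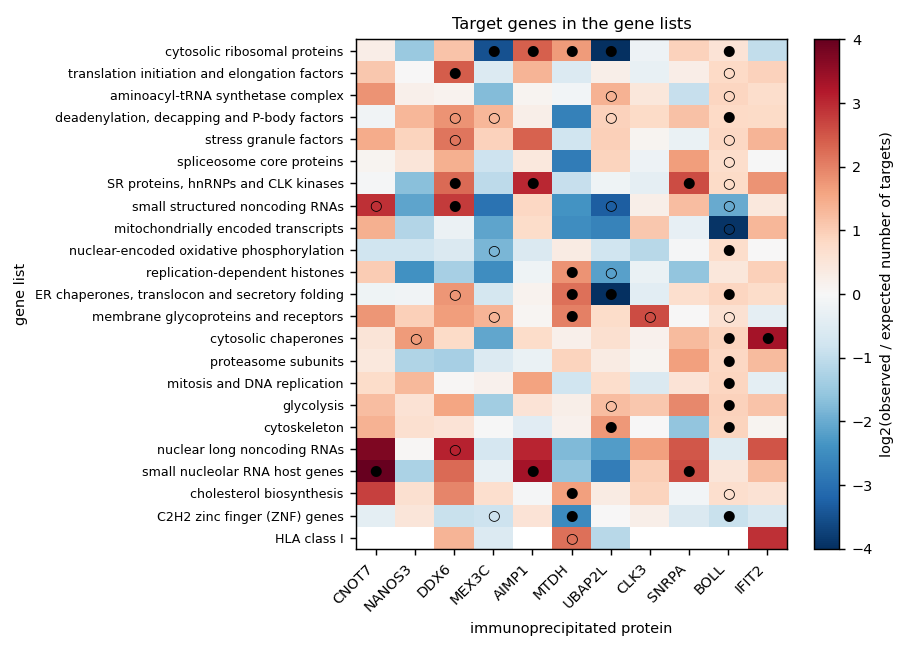
Log2 of the observed over the expected number of target genes (colour, limited to ±4) for each protein and gene list with at least 1 call, with 0 targets drawn as 0.5 and blank cells where fewer than 5 members were measured. Filled circles mark calls made by Fisher's exact test and by matched random lists, and open circles calls by Fisher's exact test alone; the ER genes are higher for MTDH (39 of 45) and lower for UBAP2L (0 of 44).

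The last comparison between proteins asked which pairs shared target genes. Of 91 pairs, 51 shared more targets than independent sets would and 2 shared fewer (Fisher's exact test, adjusted over the pairs). The Mantel-Haenszel strata of listed peaks kept 43 of the 51 and gave 7 pairs with fewer. Among the calls lost was that of UBAP2L and CLK3, whose odds ratio fell from 3.437 to 1.045. CNOT7 and DDX6 shared 100 genes against 6.94 expected (odds ratio 48.9, adjusted p = 2.01e-96), and 87 of them without positions enriched with 4 or more proteins. CNOT7 and AIMP1 shared 39 against 3.45 (odds ratio 17.2), and DDX6 and AIMP1 73 against 11.5 (odds ratio 9.37). NANOS3 shared 813 genes with BOLL against 560.6 (odds ratio 5.10) and 414 with UBAP2L against 200.1 (odds ratio 3.42). With strata of listed peaks (Mantel-Haenszel), these odds ratios were 42.6, 15.7, 6.79, 3.85 and 2.12 in the same order.

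The highest odds ratios joined proteins with few target genes: TOB2 and CLK3 (49 genes against 2.56, odds ratio 89.0), PARN and CLK3 (27 against 0.875, 78.1) and PARN and TOB2 (25 against 1.27, 54.1). Without the shared positions these pairs had 14, 3 and 3 genes in common. They were still called higher (Fisher's exact test, adjusted p = 1.73e-14, 0.00446 and 0.00518). PARN and TOB1 (16 genes) and TOB1 and IFIT2 (24 genes) then had 1 and 2, and their calls ended (adjusted p = 0.303 and 0.280, Fisher's exact test). Over all pairs, 33 remained higher without these positions.

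MTDH and UBAP2L, both bound to coding sequence, shared fewer genes than independent sets would, 198 against 342.8 (odds ratio 0.444, adjusted p = 6.79e-25, Fisher's exact test). With strata of listed peaks the odds ratio was 0.254. CLK3 and BOLL shared 56 against 72.2 (odds ratio 0.477, adjusted p = 0.00114).

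The transcript of each protein's own gene was examined in every library. NANOS3 had 53 and 48 enriched peaks in its own gene in the 2 replicates and BOLL 48 and 48, all in the CDS, in genes of the germline. UBAP2L had 21 and 57 in its CDS, IFIT2 17 and 8 in its CDS, and PARN 4 and 10. MEX3C had 13 and 14, of which 12 and 12 lay in the 3' UTR, and SNRPA 11 and 8, all in the 3' UTR. MTDH had 4 and 7, TOB2 0 and 1, and DDX6 1 and 0. CNOT7, AIMP1, CLK3 and TOB1 had none. For TOB1 31 and 33 peaks were listed in its own gene, all in the CDS, with a highest log2 fold of 1.43 and 1.65. For several proteins these counts do not check the labels, because the BOLL libraries held similar or larger numbers of enriched peaks in the same gene: 14 and 10 in TOB2, 8 and 10 in MTDH and 6 and 6 in PARN. The TOB2 gene also held 4 and 4 in the NANOS3 libraries and 10 in UBAP2L replicate 2.

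The genes BOLL, NANOS3 and IFIT2 also held enriched peaks in libraries of other proteins. In the BOLL gene there were 33 and 40 in the TOB2 libraries, 33 in PARN replicate 2, 8 in TOB1 replicate 1 and 4 in CLK3 replicate 2. In the NANOS3 gene there were 18 and 8 in the MEX3C libraries, and in the IFIT2 gene 3 in TOB2 replicate 1. The highest log2 fold in the BOLL gene was 10.24 in TOB2 replicate 1, and 5.28 in BOLL replicate 1, each over its own input.

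**Figure D5:**
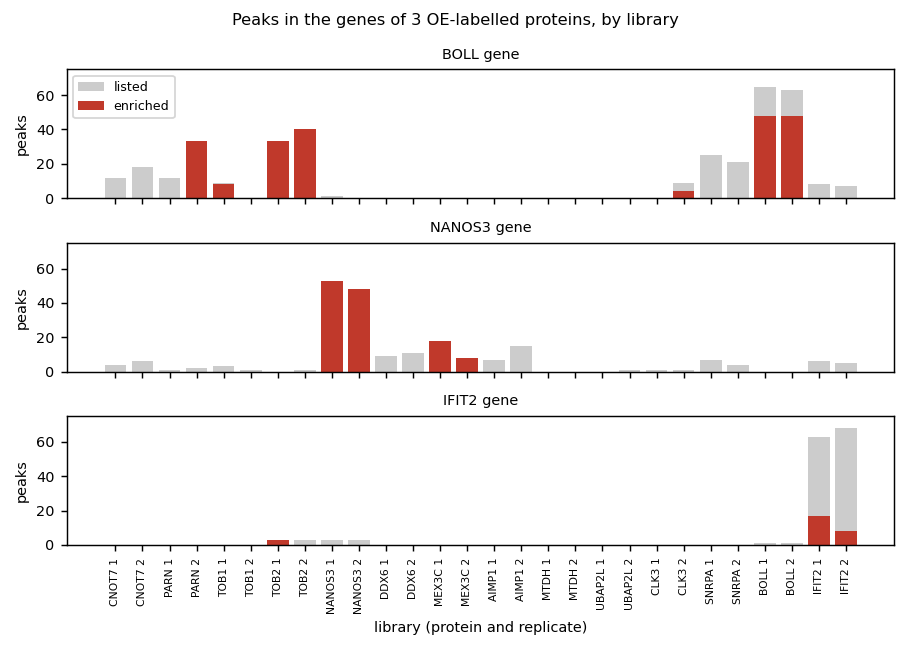
Number of listed (grey) and enriched (red) peaks in the genes BOLL, NANOS3 and IFIT2 in each of the 28 libraries, named by protein and replicate. Besides the library pair of each protein itself, enriched peaks stand in TOB2, PARN, TOB1 and CLK3 libraries for BOLL, in both MEX3C libraries for NANOS3 (18 and 8) and in 1 TOB2 library for IFIT2 (3).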

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

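The test on the transcript region and the test on peaks at the p cap were chosen only after the result was seen. Enriched peaks in the genes of proteins with the OE prefix stood out because they appeared in libraries of other proteins, outside every comparison of the design. The BOLL gene held 33 in TOB2 replicate 1, 40 in TOB2 replicate 2, 33 in PARN replicate 2, 8 in TOB1 replicate 1 and 4 in CLK3 replicate 2, and the NANOS3 gene held 18 in MEX3C replicate 1 and 8 in MEX3C replicate 2. In the other replicates of PARN, TOB1 and CLK3 the BOLL gene had 0 enriched peaks. Listed CDS peaks of these genes also stood in libraries of the same sequencing lane. For BOLL, CNOT7 held 11 and 18 and SNRPA 24 and 20, none enriched, with highest log2 folds from -1.059 to 0.491. For IFIT2, the NANOS3 and TOB2 libraries held 3 each (enriched in TOB2 replicate 1), and for NANOS3 the IFIT2 libraries held 6 and 5. The enriched BOLL and NANOS3 peaks named above lay in libraries of other lanes. Listed CDS peaks that were not enriched stood in other lanes too. For BOLL, PARN replicate 1 held 12, the IFIT2 libraries 8 and 7, and NANOS3 replicate 1 held 1. Their highest log2 folds were 1.835, 3.73, 3.28 and 0.444 in that order. For NANOS3, the PARN libraries held 1 and 2. Whether lane plays a part was not tested.

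Of the 48 reproducible positions in the BOLL gene, 47 were enriched in both TOB2 libraries. Of the 100 strongest BOLL peaks in other genes, 3.0% were enriched in both TOB2 libraries. This met the bound set against a carry-over of the BOLL libraries as a whole. Those peaks were ranked by fold over input and not by reads, so how much of them a carry-over would bring is unknown. The value therefore does not exclude a carry-over. The tables argue against endogenous transcripts. Of the 147 enriched peaks in these genes, the 3 of IFIT2 included, 100% lay in the CDS and none in a UTR or intron. Among BOLL peaks at the p cap in other genes, 4.8% (27 of 562) were enriched in both TOB2 libraries. This met the bound set against a carry-over limited to the read-richest RNA. The cap hides how much richer the BOLL gene itself is, so this test does not exclude it either. The test for double-stranded plasmid or amplicon DNA gave 0.0% of peaks with an enriched peak on the opposite strand, but it decides nothing, because the lists hardly hold peaks off the annotated strand (0.037% outside genes), so DNA of a construct cannot be told apart from its RNA here. For BOLL in TOB2, a candidate explanation is a construct holding only the coding sequence, present by a route that was not tested, and carry-over is not excluded. Carry-over was not tested for PARN, TOB1 and CLK3 or for NANOS3 in MEX3C and IFIT2 in TOB2 and stays open there too. No biological explanation was tested.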

How the results depend on the processing

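The setting without positions enriched with 4 or more proteins was chosen only after the data were seen, and the others were fixed before the data were examined. With the looser fold, reproducible peaks numbered 1208 for CNOT7, 1396 for PARN, 2098 for TOB1, 7068 for NANOS3, 3578 for DDX6, 9539 for MEX3C, 1809 for AIMP1, 30169 for UBAP2L, 5541 for SNRPA, 66343 for BOLL and 1876 for IFIT2. Gene list calls rose to 141 higher, and pairs to 79 higher and 5 lower, as more genes became targets by construction. Of the 45 higher list calls 44 remained, but of the 11 lower calls only 6. Those of ribosomal protein genes for MEX3C and histone genes for UBAP2L turned to higher, and those of ER and ribosomal protein genes for UBAP2L and of oxidative phosphorylation genes for MEX3C ended; the cause was not tested. With the stricter p, DDX6 had 653 peaks and AIMP1 353, and with the reciprocal overlap UBAP2L had 7532. Without shared positions PARN had 70, TOB1 75, TOB2 173 and IFIT2 179, and 33 pairs shared more targets. With matched lists 28 gene list calls were higher, and the Mantel-Haenszel strata gave 7 pairs with fewer shared targets; the cause was not tested. One replicate alone needs no second library, so its counts are larger by construction: 737 to 1559 for CNOT7, 585 to 904 for PARN, 672 to 1052 for TOB1, 428 to 582 for TOB2, 3944 to 7950 for NANOS3, 2862 to 2899 for DDX6, 5266 to 6583 for MEX3C, 1432 to 1927 for AIMP1, 10724 to 13051 for MTDH, 22342 to 47201 for UBAP2L, 1285 to 2144 for CLK3, 2828 to 3264 for SNRPA, 51286 to 51565 for BOLL and 559 to 1353 for IFIT2.

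The limma contrasts that were set aside made 9969 calls over the 14 proteins (adjusted p threshold 0.05), 16579 with no centring, and 4979 to 5142 with 1 replicate of the protein left out, where the lone library is assumed to vary like the others. Replicate numbers do not pair these samples: deviations of same-numbered libraries had a median correlation of -0.003 over 91 protein pairs (from -0.08 to 0.04, across 2790 genes), and with the replicate number as a block limma made 9931 calls. In the regional tests the block gives the same differences by construction, such as 36.42 points for the 3' UTR by OE prefix, and it changed no call. Replicate agreement stayed past its threshold with correlations (mean 0.671) and the looser fold (0.532), and no regional difference passed in any setting. The motif search and its window alternative were not run. Depth is unknown, and the TOB2 lists, with 11185 and 24326 peaks, limit the pair tests with TOB2 to at most 3457 genes and its gene list tests to 3522.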

Other observations

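The test on abundant RNA, the comparison of pairs with the OE prefix and the cut-off of 6 proteins were chosen only after the result was seen. Several microRNA and small RNA loci were enriched with many proteins. The MIR222 locus (X:45606435-45606494) had enriched peaks of 9 proteins in 18 libraries, MIR221 (X:45605601-45605652) of 6 proteins in 8 libraries and MIR17HG (13:92003188-92003217) of 6 proteins in 8 libraries. The snoRNA host gene GAS5 was enriched with CNOT7, DDX6, AIMP1, MTDH, SNRPA and IFIT2, and the TOB1 3' UTR held 7 enriched MEX3C peaks in each replicate. Target genes of the 4 proteins with the OE prefix overlapped with a median log2 odds ratio (Mantel-Haenszel, strata of listed peaks) of 2.23 over their 6 pairs, against 0.61 over the other 85 pairs. Of 1001 choices of 4 proteins, 71 gave a difference as large (exact permutation test, one-sided, p = 0.0709).

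Positions enriched with many proteins were often short. There were 51 positions with enriched peaks of at least 6 proteins. Among them were ZNF512B (CDS) and ERCC1 (intron) with 11, SIN3B (intron) with 10, and C12orf57, FGFR3, JHDM1D, RAB1B and THSD7A with 9. The 1107 enriched peaks at the 51 positions had a median width of 10 nt, against 48 nt for enriched peaks of 1 protein alone. That median counts every peak, and SIN3B (77), FGFR3 (74) and ERCC1 (64) held the most. Other positions were not short, with a median width of 123 nt at MAGED2, 95.5 nt at SEMA4C and 81 nt at ADAMTS1. The bounds set for abundant RNA captured in every immunoprecipitation assumed that it would be seen above all with the peak-richest proteins. That assumption was not tested, and such RNA could instead stand out where enriched peaks are few, so the bounds cannot decide. Enriched peaks of UBAP2L stood at 49.0% and of BOLL at 45.1% of the positions, between the bounds set for and against it. Of the proteins with fewer enriched peaks, some stood at more of the 51 positions than UBAP2L (25) and BOLL (23). These were TOB1 (37), IFIT2 (36), PARN and MEX3C (35 each), NANOS3 and CLK3 (31 each), and TOB2 and MTDH (28 each). Others stood at fewer, namely DDX6 (21), AIMP1 (18), CNOT7 (17) and SNRPA (2). These counts go both ways, met no bound set for abundant RNA and do not decide on it. Double-stranded DNA was tested by enriched peaks on the opposite strand, found for 0.0% of them, which decides nothing because the lists hardly hold peaks off the annotated strand. Both technical explanations therefore stay open, and no biological explanation was tested.

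ER genes were targets of MTDH and not of UBAP2L, although both proteins bound coding sequence. They were not particular to MTDH, as the ER list was also called higher for BOLL by both tests and for DDX6 by Fisher's exact test alone. The tables argue against the number of listed peaks per gene in the MTDH libraries as the whole explanation. The ER list held 2.198 times the MTDH targets of matched random lists, none of which reached it. This gave p = 0.0002, the smallest possible (permutation test with random lists, two-sided). It is the matched result by which the list was called above, so it adds no separate evidence. Those peaks were listed in immunoprecipitations, so their number does not measure transcript level or length. The tables also argue against coding-sequence binding alone being enough, because the ratio for UBAP2L over genes listed in all 4 libraries was 0.0 (0 of 44 against 7.25). At the looser fold, however, 13 of 44 were UBAP2L targets, which was no longer called lower. UBAP2L was the only other coding-sequence protein set against MTDH in this way. Ribosomal protein genes (45 of 74) and histone genes (26 of 40), whose products are not secreted, were MTDH targets too. What stays open is which property of these mRNAs is involved, and preferential binding of MTDH to mRNAs translated at the ER is a candidate explanation that fits the ER values, leaves those genes aside and was not tested itself.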
